A study of Mus musculus with 12 samples.

How the data were processed

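Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in CD45.2+ bone marrow cells of C57BL/6 mice. The 12 libraries fell into 4 groups of 3: wild-type marrow (Control), and leukaemic cells carrying BRD9-NUTM1 (BN1), MLL-AF9 (MA9) or MLL-ENL (ME). Per the labels' protocols, 150000 FACS-sorted cells per sample were transposed with an Active Motif kit. The labels gave replicate numbers 1 to 3 per group and did not say whether these were separate animals or cultures. A p-value from regrouped libraries therefore measures only the spread between these samples. Tests against random or other genes held the calls of the libraries fixed, so their p-values measure only the spread between genes. Nor did the labels say whether Control cells were sorted by the same gate beyond CD45.2+. A loss of B cell, erythroid or neutrophil regions against Control therefore includes any difference in the cells sorted. The same holds for a gain of Hoxa, progenitor or granule gene regions.

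The deposited data were 1 list of peaks per library, in narrowPeak layout. Per the submitters' processing notes, the tools were Bowtie2 2.5.4, Picard 3.2.0, deepTools 3.5.1 and Genrich, for which no version was given, on the mouse build GRCm38 (mm10). Peak signal was deposited by the authors for every peak and was never below 200.0. It was read as Genrich's area under the −log10 p curve because of that minimum; the notes gave no options, and signal percentiles and lists of equal length rest on this reading. The deposited −log10 p and −log10 q columns carried the authors' peak significance, and the deposited score was a capped display value that was not used further. None of these columns was put on a common scale between libraries, so signal and significance were used only as percentiles within a library or as thresholds. Read numbers were not part of the lists, so sequencing depth is unknown and no interval for counting error could be given. A region missing from a list was not called there, which does not show that it was closed.

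Peaks on chromosomes 1 to 19 were used. No list held a peak on X, Y or the mitochondrial genome, so genes there could not be studied, and peaks on unplaced sequences entered 1 alternative only. Overlapping peaks of the 12 libraries (1 bp or more) were merged into regions. A region was called gained in a comparison when all libraries of the first group and no library of the second group had a peak in it, and lost in the reverse case. The comparisons were BN1, MA9 and ME each against Control, the 3 pairs of leukaemias, BN1 against MA9 and ME together, and all leukaemias against Control.

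Genes came from a RefSeq table of GRCm38.p6. It gave gene spans without strand, exons or sequence. The planned transcription start sites were therefore replaced by gene ends: a peak within 1 kb of either end of a protein-coding gene counted as a gene-end peak, and a region went to the gene with the nearest end. The share of peaks inside gene bodies replaced the planned shares in exons, introns and intergenic DNA. The planned comparison of motif shares at summits needed the genome sequence and was not run.

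Gene lists were fixed before the data were examined: the Hoxa cluster; Hox cofactors and MLL fusion targets; the Bmi1 neighbourhood; fusion partners and complexes; stem and progenitor cells; B cells; T cells; NK cells; neutrophil maturation; promyelocyte granules; monocytes and macrophages; dendritic cells; erythroid cells; megakaryocytes; mast cells, basophils and eosinophils; interferon response; housekeeping promoters; and genes silent in blood. Measured members numbered 18 of 20 erythroid genes, 14 of 16 interferon response genes and 18 of 20 housekeeping genes; Gata1, Alas2, Hprt and Pgk1 lie on X, and Mx1 and Mx2 are annotated as pseudogenes. All members of the other lists were measured. The list named Bmi1 neighbourhood held 9 genes near Bmi1 on chromosome 2 and Spag6l, which lies on chromosome 16. For each list and direction, the number of genes with a gained or lost region was set against 10000 random lists matched on the number of regions per gene (two-sided permutation p), with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Random lists treat genes as independent, which neighbours such as the Hoxa genes are not. A further test took, per library, the log2 odds of a gene-end peak in the list against all other genes, with 0.5 added to each cell.

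Differences across all 4 groups were tested by an exact permutation test over the 15400 splits of 12 libraries into 4 groups of 3, for which the smallest possible p is 6.49e-05. Differences of 3 libraries against 3 were tested two-sided by an exact permutation test that cannot go below 0.1. Similarity of libraries was the Jaccard index of covered bases. No test was made per region. With 3 libraries against 3, calls in all of one group and none of the other cannot reach the threshold; the pooled comparisons were treated in the same way.

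Genes named in the text were chosen by a rule fixed before the data were examined. It took Hoxa9, Hoxa10, Meis1, Bmi1, Brd9, Nutm1, Kmt2a, Mllt3, Mllt1 and Ptprc always. Per comparison and list it took up to 4 genes in each direction with the highest mean signal percentile, and per comparison the 10 strongest gained and lost regions. Other genes are named as chosen after their values were seen.

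Alternatives fixed before the data were examined were a stricter significance (−log10 p of at least 7.07, the median over all peaks), lists of equal length (the 3011 peaks of highest signal in each library), leaving out each library, a replicate block, and other overlap, window, assignment and replicate rules. Further tests were added after the data were seen. In the main addition, each gene's strongest region in the group with the longer lists was asked for in the other group and compared with genes whose strongest region had a similar summit percentile (in deciles) and lay within or beyond 1 kb of a gene end; it is called the strength-matched test, and 10000 random draws gave its permutation p. The others were gene families by symbol stem, called regions per chromosome, and counts of called list genes.

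Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures Matplotlib 3.10.9. The region and list steps were tested on simulated data made from the 23046 Control regions as an MA9 against Control comparison, with 200 gained and 258 lost regions seeded. Recovery was 100.0% without misses. With up to 20% of peaks missing per library, 73.5% of the gained and 73.3% of the lost regions were recovered, with 30 false gains and 20 false losses, the seeded list was called and 0 of 20 random lists were. Both simulated groups had the same miss rate, so these counts do not cover false losses from unequal list lengths, as in BN1 and ME.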

Results

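Open chromatin was compared between wild-type bone marrow and leukaemic marrow cells driven by 3 fusion proteins. BRD9-NUTM1 (BN1) joins BRD9, a bromodomain subunit of a SWI/SNF chromatin remodelling complex, to NUTM1, a protein normally made in testis that recruits the histone acetyltransferase p300. MLL-AF9 (MA9) and MLL-ENL (ME) join the histone methyltransferase KMT2A (MLL) to MLLT3 (AF9) or MLLT1 (ENL), subunits of elongation complexes. The measurement was ATAC-seq on sorted CD45.2+ cells, with 3 libraries per group and 12 peak lists. The peak lists carried no read numbers, so the depth behind a call is unknown. A p-value from regrouped libraries measures only the spread between these samples, and one from random or other genes only the spread between genes.

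The groups differed in the number of accessible regions called. Control libraries held 27024 ± 1310 peaks (mean ± SD, n = 3), MA9 libraries 32615 ± 858, ME libraries 9275 ± 632 and BN1 libraries 3567 ± 634. The groups' ranges did not overlap, and an exact permutation test across all 12 libraries gave p = 6.49e-05, the smallest possible. Peaks covered 12.9 Mb of the genome in Control, 15.01 Mb in MA9, 3.89 Mb in ME and 1.45 Mb in BN1. Median peak width was 364 bp in Control, 329 bp in MA9, 330.0 bp in ME and 347 bp in BN1 (exact permutation p = 0.0013 across the 12 libraries). Any comparison of calls between groups is read against these list lengths.

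**Figure D1:**
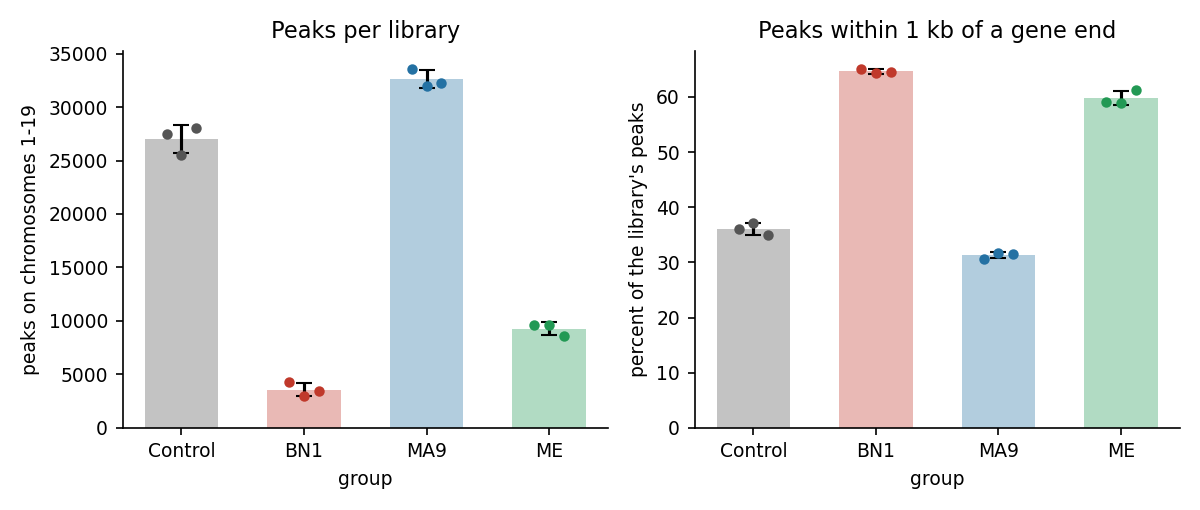
Peaks per library on chromosomes 1 to 19 (left, number) and share of peaks within 1 kb of a gene end (right, percent) for the 4 groups. Bars are means, whiskers SD and points the 3 libraries; BN1 libraries have 3011 to 4258 peaks, against 25541 to 28023 in Control.

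The 12 lists merged into 43905 regions, of which 2407 were called in every library. All 3 libraries of a group shared 23046 regions in Control, 27412 in MA9, 7528 in ME and 2478 in BN1. The short lists were nested in the long ones: 98.3% of the BN1 regions were also called in all 3 Control libraries, 99.3% in all 3 MA9 libraries and 98.3% in all 3 ME libraries, and 99.3% of the ME regions were called in MA9. Regions called in every library of a group and in none of the other 9 numbered 5313 in Control, 8577 in MA9, 12 in ME and 4 in BN1. Libraries of a group resembled each other, with a mean Jaccard index of covered bases of 81.1% in Control, 79.2% in MA9, 82.6% in ME and 66.4% in BN1. Between groups it was 43.8% for Control and MA9, 25.8% for Control and ME, 10.7% for Control and BN1, 25.5% for MA9 and ME, 35.2% for BN1 and ME, and 9.49% for BN1 and MA9. The within-group mean exceeded the between-group mean by 0.523 (exact permutation p = 6.49e-05, the smallest possible). Counted instead as the share of the shorter list's peaks that overlapped the longer list, the difference was 0.0192 and no longer passed (exact permutation p = 0.235), as short lists lay inside long ones.

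In lists of equal length, ME lay closer to either other leukaemia than to Control, which in the deposited lists held for BN1 but not for MA9. The Jaccard index among the 3011 strongest peaks was 47.9% for BN1 and ME, 45.1% for MA9 and ME, and 26.3% for BN1 and MA9. With Control it was 38.2% for MA9, 31.9% for ME and 24.5% for BN1. Gene ends took 64.6 ± 0.434% of BN1 peaks and 59.8 ± 1.31% of ME peaks, against 36.0 ± 1.047% in Control and 31.3 ± 0.595% in MA9 (SD, n = 3; exact permutation p = 6.49e-05, the smallest possible). At equal length the BN1 share was below Control, 66.2% against 69.5%, and MA9 (74.3%) and ME (75.1%) were above it (exact permutation p = 0.000714 across all 4 groups). The difference between BN1 and Control went from 28.6 to -3.25 percentage points, and at equal length the libraries of both groups overlapped (64.3 to 68.8% in BN1, 67.8 to 71.2% in Control; exact permutation p = 0.2). In the lists as deposited, gene bodies held about as large a share of BN1 as of ME peaks; the values per library ran from 77.6% to 79.4% in BN1 and from 78.3% to 79.8% in ME.

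The comparison of BN1 with Control asked which regions of normal marrow chromatin were called in BRD9-NUTM1 leukaemia. Among the regions with the highest signal in Control, those over the neutrophil calprotectin genes S100a9 and S100a8, the granule gene Ngp, the MHC class II chaperone Cd74 and the chemokine receptor Cxcr4 had no peak in any BN1 library. The same held for regions over the histone genes H2bc7, H2ac13 and H3c3, over the actin regulator Coro1a and near Ly6e. The S100a9 region (chromosome 3, 90691227 to 90696108) had a mean signal percentile of 99.97 within Control libraries, and the S100a8 region (90668592 to 90673662) one of 99.9. In total 19033 regions were lost and 36 gained, and 68.4% of the lost regions lay over 1 kb from a gene end.

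Lost regions lay near lineage genes of every kind tested. They were assigned to 17 of 19 B cell genes with a region, among them the B cell coactivator Pou2af1 (mean percentile 93.1), Cd72 (85.8), the surface antigen Ms4a1 (85.3) and the B cell master regulator Pax5 (83.8, with 7 lost regions). Erythroid genes with lost regions numbered 17 of 18 (16.3 in random lists), including the anion exchanger Slc4a1 (93.2). All 18 neutrophil maturation genes had them (17.1 in random lists), including Retnlg (98.5). Lost regions were also nearest to 13 of 14 Hox cofactors and MLL fusion targets (Mef2c 94.2, Mn1 89.6, Myc 84.5 and Pbx3 84.1), against 13.4 in random lists. Stem and progenitor genes had them at 9 of 14 against 11.8, among them Lmo2 (89.0), Cd34 (87.8) and Sox4 (84.5). Others were nearest to the interferon regulator Irf7 (94.4) and the von Willebrand factor gene Vwf (94.4). No list stood apart from random lists: 0 of 18 passed among lost regions with Benjamini-Hochberg adjustment, 2 had an unadjusted permutation p under 0.05, and Fisher's exact test passed 0. Random lists already had lost regions at most genes, so these tests could hardly show an excess. At the stricter peak significance, promyelocyte granules (adjusted p = 0.0072) and housekeeping promoters (adjusted p = 0.0216) passed in the permutation test as lost in fewer genes than random lists.

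The regions gained in BN1 were few, and 94.4% lay over 1 kb from a gene end. The strongest lay 0.646 kb from LOC108167320 on chromosome 9 (124439114 to 124441034; mean percentile 99.7 in BN1), 5.37 kb from Mepe (90.4) and 27.9 kb from the endothelial cadherin gene Cdh5 (87.5), with 2 further gained regions near Cdh5 (79.1 and 76.4). Others lay near Ano6 (86.1), Pura (82.1) and Gramd1b (76.3). No list passed among gained regions (0 of 18 adjusted, 0 unadjusted, 0 by Fisher's exact test). With lists of equal length the counts were 510 gained and 746 lost, but equal lengths bring both counts close together whatever the cause of the losses. Calls in BN1 also followed strength: 68.4% of the strongest decile of Control regions were called in all 3 BN1 libraries and 0.607% of the weakest decile. Against genes of equal strength, chosen as a test after the data were seen, 0 of 15 lists differed between Control and BN1, with 0 at an unadjusted permutation p under 0.05. Few calls were predicted for lineage lists: 0.705 of 17 B cell genes, 1.7 of 18 neutrophil maturation genes and 1.99 of 18 erythroid genes. The test could therefore hardly show a loss there.

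**Figure D2:**
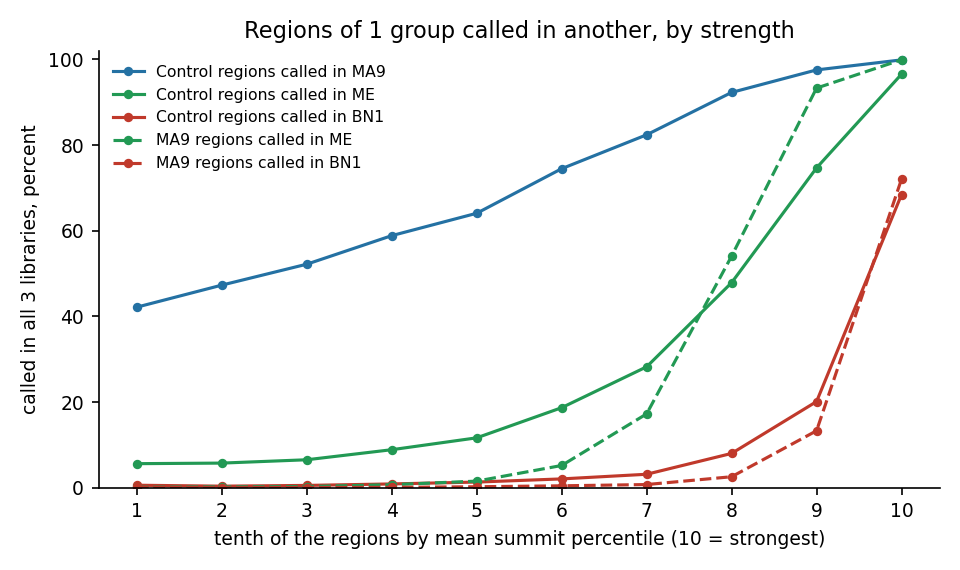
Share of the regions of a group (vertical axis, percent) that were called in all 3 libraries of another group, by decile of the regions' mean summit percentile (horizontal axis, 10 strongest); solid lines are Control regions and dashed lines MA9 regions. In the strongest decile of Control regions, 99.9% were called in MA9, 96.5% in ME and 68.4% in BN1.

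The comparison of MA9 with Control asked how MLL-AF9 leukaemia differed from normal marrow with lists of similar length. The mix of cells in each group was not measured, so gains and losses against Control cannot be told apart from a different mix. Chromatin over the Hoxa cluster, whose homeobox genes maintain immature blood cells, was called in MA9 and nearly uncalled in Control: MA9 libraries had 18 to 20 peaks over chromosome 6, 52135367 to 52280880, and Control libraries 1 or 2. Regions assigned by nearest gene end to Hoxa9 (52225190 to 52227502; mean percentile 95.0), Hoxa3 (92.3), Hoxa7 (91.5) and Hoxa10 (90.04, 4 regions) were gained. B cell and erythroid regions went the other way, with lost regions at 17 of 19 B cell genes and 16 of 18 erythroid genes. There were 9252 gained and 5317 lost regions, and 87.9% of the gained and 87.0% of the lost regions lay over 1 kb from a gene end.

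Gained regions near progenitor and leukaemia genes included those of the cell cycle kinase Cdk6 (89.3, 10 regions), the transcription factor Myb (87.1, 4 regions), the stem cell factor receptor Kit (87.0), Mn1 (80.7), Jmjd1c (79.4), Gata2 (74.9) and Erg (71.3, 7 regions). The granule protease genes Ctsg (94.8) and Prtn3 (83.0) and the myeloperoxidase gene Mpo (75.3), all transcribed in promyelocytes, also had gained regions. The strongest gains genome-wide lay near Dyrk1a (99.0), Zdhhc14 (98.7), Ltbp2 (98.1), Actr3 (97.0) and the DNA demethylase Tet2 (96.0, 81.1 kb away), and over Srf (95.2). By number of regions per gene the Hoxa cluster did not pass (6 of 7 genes gained, 2.66 in random lists, adjusted permutation p = 0.0672; 0.0115 without Control replicate 1). Against genes of equal strength it did: 1 of 7 Hoxa genes had its strongest MA9 region called in all 3 Control libraries where 6.55 were predicted (adjusted permutation p = 0.0036), the exception being a Hoxa9 region (52221166 to 52222731). The Hoxa genes are neighbours in 1 cluster rather than independent, so these p-values may be too small. Promyelocyte granule genes with gained regions numbered 10 of 13 against 6.396 in random lists (adjusted permutation p = 0.192; 0.0324 with regions within 10 kb of the gene), and stem and progenitor genes 11 of 17 against 9.32 (adjusted permutation p = 0.734). By Fisher's exact test, which does not match genes on their number of regions, promyelocyte granules (adjusted p = 0.0384) and Hox cofactors and MLL fusion targets (adjusted p = 0.000984) passed among gains; the latter had gained regions at 14 of 16 genes against 11.5 in the random lists (adjusted permutation p = 0.572).

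Among lost regions 5 lists passed, all of maturing lineages, with Benjamini-Hochberg adjustment of permutation p-values. B cell genes lost regions at 17 of 19 members where random lists gave 4.86 (adjusted permutation p = 0.0024), including Pou2af1 (93.1), Ms4a1 (85.3) and Pax5 (83.8, 6 regions). Erythroid genes lost regions at 16 of 18 (5.31 in random lists; adjusted permutation p = 0.0024), among them Slc4a1 (93.2), the cytoskeletal adaptor Ank1 (77.5) and Hemgn (74.4). Neutrophil maturation genes lost regions at 13 of 19 (6.81; adjusted permutation p = 0.0168), including S100a9 (99.97), Retnlg (98.5), the chemokine receptor Cxcr2 (93.5) and the lactoferrin gene Ltf (89.4). All 6 megakaryocyte genes with a region had a lost region (2.66; adjusted permutation p = 0.0168), for example the platelet genes Selp (54.7) and Gp9 (52.4), and so did 7 of 9 dendritic cell genes (2.89; adjusted permutation p = 0.0351), among them Spib (79.3). Other strong losses lay over Lyz2 (99.4), the haemoglobin gene Hba-a1 (98.7) and Tmem184a (95.1). Conversely, 3 lists had gained regions at fewer genes than random lists: B cells (1 of 19 against 8.31; adjusted permutation p = 0.0024), neutrophil maturation (3 of 19 against 10.7; adjusted permutation p = 0.0036) and erythroid cells (3 of 18 against 8.996; adjusted permutation p = 0.0247).

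The B cell and erythroid losses also passed at equal strength: 3 of 17 B cell genes had their strongest Control region called in MA9 where 14.1 were predicted, and 4 of 18 erythroid genes where 15.3 were (both adjusted permutation p = 0.0018). Neutrophil maturation genes did not pass there (12 of 18 called, 15.7 predicted, adjusted permutation p = 0.162), nor did dendritic cells (7 of 9, 7.92 predicted) or megakaryocytes (4 of 6, 5.37 predicted). The dendritic call rested on particular libraries: its adjusted permutation p was 0.0736 without Control replicate 2, 0.0585 without Control replicate 3 and 0.0648 without MA9 replicate 3. Without MA9 replicate 3, the lower numbers of gained regions gave adjusted permutation p-values of 0.074 for neutrophil maturation and 0.121 for erythroid cells, and the latter also lost its call without Control replicate 3 (0.0585). Neither of these passed by Fisher's exact test (adjusted p = 0.116 and 0.149) or with a peak in 2 of 3 libraries (adjusted permutation p = 0.0936 and 0.0552), and erythroid cells did not with regions within 10 kb of the gene (0.811) or 50 kb of a gene end (0.056). At the stricter peak significance none of the 3 lists passed among gains (B cells 0.209, neutrophil maturation 0.378, erythroid cells 0.804, adjusted permutation p). Among losses, neutrophil maturation (0.0828), dendritic cells (0.209) and megakaryocytes (0.378) did not pass there, nor did dendritic cells with a peak in 2 of 3 libraries (0.104). By Fisher's exact test all 5 lists passed among losses. At equal list length, 732 regions were gained and 710 lost and 0 lists passed in either direction. Only 3 B cell, 3 erythroid, 3 megakaryocyte and 1 dendritic cell genes still had a region in those lists, so these lists could hardly pass. Of 7 neutrophil maturation genes with a region, 5 had a lost region (0.963 in random lists, adjusted permutation p = 0.0576).

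**Figure D3:**
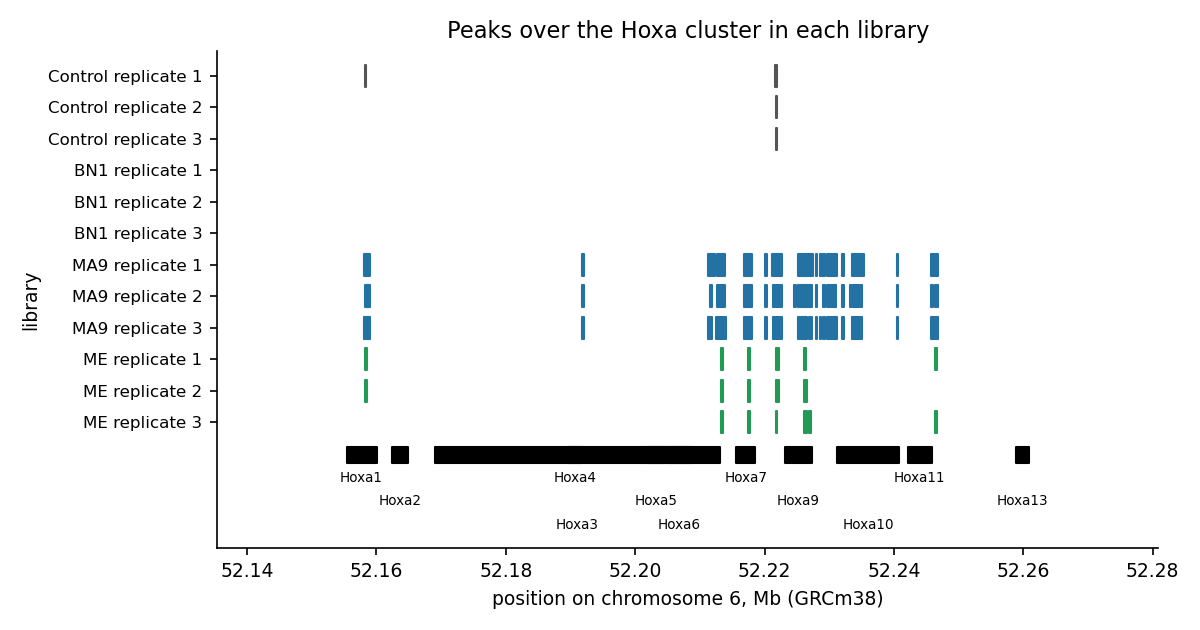
Peaks over the Hoxa cluster on chromosome 6 (horizontal axis, position in Mb, GRCm38) in each of the 12 libraries (1 line each, coloured by group), with the annotated gene spans in black underneath. MA9 libraries carry 18 to 20 peaks, ME libraries 5 to 7, Control libraries 1 or 2 and BN1 libraries 0.

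The comparison of ME with Control asked the same of MLL-ENL leukaemia, whose mean list length was 0.343 of that of Control. Despite the shorter lists, regions assigned to Hoxa7 (mean percentile 54.5 in ME), Hoxa9 (50.3) and Hoxa3 (13.3) were gained, and ME libraries had 5 to 7 peaks over the cluster. These names follow the nearest annotated gene end. The first peak of ME replicate 3 over the cluster began at 52213268, so the region named Hoxa3 lay there or beyond, beside the other 2. Regions of the granule genes Mpo (78.1, 2 regions), Prtn3 (51.5), Ctsg (47.6, 2 regions) and Ms4a3 (36.3) were gained as well. Both lists passed among gained regions: the Hoxa cluster with 3 of 5 genes (0.11 in random lists) and promyelocyte granules with 4 of 11 genes (0.355), each with an adjusted permutation p of 0.0144. As the Hoxa genes are neighbours rather than independent, the p-value of the cluster may be too small. At equal list length neither list passed, and the Hoxa cluster had 0 genes with a gained region, a difference of -0.186 genes from random lists. Only 1 Hoxa gene still had a region in those lists, so a gain there could hardly be shown. Promyelocyte granule genes with a region numbered 6, of which 3 had gained regions (1.22 in random lists).

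In all, 400 regions were gained and 14648 lost, or 779 and 809 at equal list length. Other gained regions lay near Dyrk1a (97.2), LOC108167320 (96.3), Ano6 (90.7), Actr3 (89.6), Lonrf1 (89.3), Kif21a (86.6) and Zdhhc14 (85.3), and, of the list genes, near Kit (49.3), Jmjd1c (32.1) and Gata2 (26.0). The strongest losses lay over S100a9 (99.97), S100a8 (99.9), Ngp (99.9), Cd74 (99.9), Lyz2 (99.4) and the haematopoietic adaptor gene Hcls1 (99.0). Lost regions were assigned to 17 of 19 B cell genes (13.2 in random lists), 17 of 18 neutrophil maturation genes (15.7) and 17 of 18 erythroid genes (14.4), with Pou2af1, Ms4a1, Pax5, Retnlg, Slc4a1 and Ank1 among them, as were Irf7 (94.4), Bicra (97.1), Lmo2 (89.0), Sox4 (84.5) and Myc (84.5). Of the 18 lists, 0 passed among lost regions by the adjusted permutation test, 2 did at an unadjusted p under 0.05, and 2 by Fisher's exact test (neutrophil maturation and erythroid cells, each with an adjusted p of 0.0129).

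Housekeeping promoters had lost regions at 4 of 15 genes against 8.41 in random lists (adjusted permutation p = 0.0768). They passed, as lost in fewer genes than random lists, without Control replicate 2 (0.024), without MA9 replicate 2 (0.0288), which altered only the merged regions, without ME replicate 1 (0.0456) and with a peak in 2 of 3 libraries (0.0108). Among losses, the Hoxa cluster passed with regions within 10 kb of the gene, as lost in fewer genes (adjusted permutation p = 0.0048), and dendritic cells at the stricter peak significance (adjusted permutation p = 0.036). At equal strength housekeeping promoters were called in ME about as predicted (14 of 15, 13.4 predicted, unadjusted permutation p = 0.99). B cells differed there: 0 of 17 B cell genes had their strongest Control region called in all 3 ME libraries where 5.78 were predicted (adjusted permutation p = 0.0144). Neutrophil maturation (3 of 18, 8.18 predicted) had an adjusted permutation p of 0.0558, interferon response (2 of 9, 5.37 predicted) one of 0.101 and erythroid cells (3 of 18, 6.82 predicted) one of 0.201. The S100a9 region, named because it was the strongest loss, was absent from all ME libraries although 96.8% of the 845 genes of comparable strength had theirs called. As the region was picked for its loss, this share is no test of it.

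**Figure D4:**
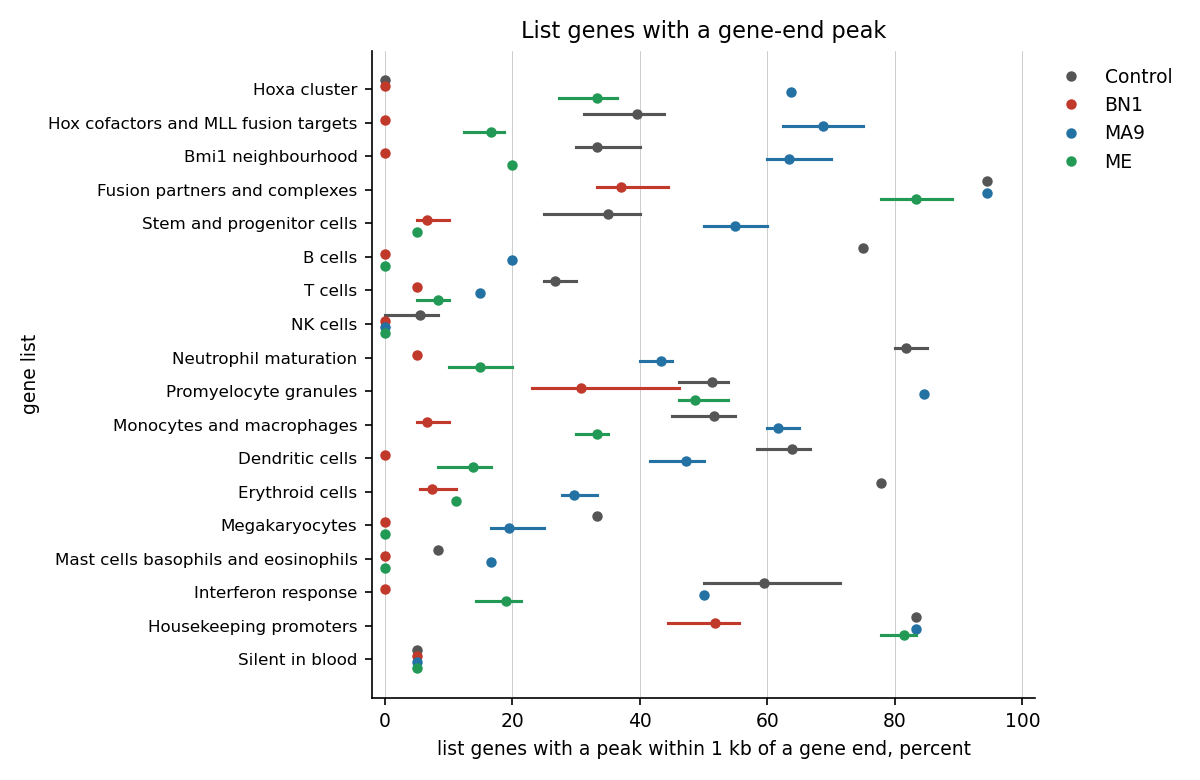
Share of each list's measured genes with a peak within 1 kb of a gene end (horizontal axis, percent) for the 18 lists, by group; points are means of 3 libraries and lines run from the lowest to the highest library. MA9 libraries call 7 of 11 Hoxa genes and Control and BN1 libraries 0; all libraries call 1 of 20 genes silent in blood.

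The comparison of BN1 with MA9 and ME together asked what set the NUTM1 fusion apart from the MLL fusions. Hoxa genes were called in both MLL leukaemias and in no BN1 library: regions assigned by nearest gene end to Hoxa9 (mean percentile 76.3 in MA9 and ME), Hoxa7 (73.0) and Hoxa3 (52.8) were lost in BN1, and BN1 libraries had 0 peaks over the whole cluster. The Hox partner gene Pbx3 (81.4), Cdk6 (76.4), Arid1b (66.2), Gfi1 (58.6), Gata2 (50.5), Erg (49.0) and Myb (36.8) lost regions too, as did Smarcc1 (81.2), Mllt1 (79.6) and Bicral (74.2) among fusion partners and complexes. Other losses were near Stat2 (69.9), Klf1 (67.4), Ly6c2 (64.4) and Commd3 (68.8). The strongest lay near Dyrk1a (98.1), H2bc12 (97.8), H2bc7 (97.2), Smyd3 (97.1), Pecr (96.3) and Rdm1 (95.8).

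Only 4 regions were gained in BN1 against MA9 and ME, and 3536 were lost. The 4 lay 22.2 kb from Map3k4 (chromosome 17, 12249839 to 12250348; mean percentile 71.0), 14.2 kb from Tmem30c (60.2), 5.70 kb from Adgb (44.6) and 25.3 kb from Zfp64 (33.7), and no Control library had them either. At equal list length 135 regions were gained and 206 lost. No list passed in either direction (0 of 18 adjusted, 0 at an unadjusted permutation p under 0.05, 0 by Fisher's exact test); 3 of 7 Hoxa genes had lost regions against 1.79 in random lists.

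Against MA9 alone, BN1 gained 14 regions and lost 23275, among them regions over Hoxa9 (97.4), Cdk6 (99.5), Pbx3 (93.8) and Tsc22d2 (99.8). Against ME alone it gained 20 and lost 3552, with lost regions over Hoxa9 (55.3), Hoxa7 (54.5) and Pbx3 (68.9) and gained regions over Arhgap35 (81.0) and near Pura (82.1), Jag1 (47.4) and the histone demethylase gene Kdm6b (57.1); the count of gains against ME was 31 without BN1 replicate 1. In both comparisons 0 lists passed by the adjusted permutation test or by Fisher's exact test, with 1 list lost in BN1 against MA9, and 0 against ME, at an unadjusted p under 0.05. Housekeeping promoters, lost in BN1 against MA9 at 7 of 15 genes where random lists gave 12.2 (adjusted permutation p = 0.0792), passed without MA9 replicate 1 (0.0144) and without MA9 replicate 3 (0.036), as lost in fewer genes than random lists. At equal strength, 0 of 7 Hoxa genes with an MA9 region were called in BN1 and 0.449 were predicted, so the lists could not show a difference in that direction.

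The comparison of MA9 with ME set the MLL fusions against each other. The Hox cofactor Meis1 was among the genes whose MA9 regions ME lacked: 8 regions at the gene on chromosome 11 were called in all 3 MA9 libraries and none of these in ME, where 66.3% of all MA9 regions were uncalled. They included the strongest (19018359 to 19019218), which all 3 Control libraries also had, at a strength where 99.4% of the 831 comparable genes were called. Meis1 had a gene-end peak in 0 MA9 and 0 ME libraries at equal list length. Hoxa10 (90.04, 4 regions), Cdk6 (89.3, 13 regions), Myb (87.1), Lmo2 (86.0), Gfi1 (84.3) and Erg (71.3, 11 regions) also had regions in MA9 that ME lacked, whereas regions over Hoxa9, Hoxa7 and Pbx3 were shared. There were 18162 such regions and 47 of the reverse kind, near Kif21a (86.6), Sulf1 (73.9) and several predicted genes, and at equal list length 352 and 306. By the adjusted permutation test 0 of 18 lists passed in either direction, with 1 among MA9 gains at an unadjusted p under 0.05, 0 by Fisher's exact test, and 0 of 16 at equal strength.

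All leukaemias together lacked 5313 regions that every Control library had. MA9 alone lacked 5317, and the shorter BN1 and ME lists already lacked 82.6% and 63.6% of the Control regions. The set therefore nearly repeats the MA9 losses, and its list results are not separate evidence on BN1 or ME. Its regions were assigned to 17 of 19 B cell genes (4.86 in random lists, adjusted permutation p = 0.0036) and 16 of 18 erythroid genes (5.28, adjusted permutation p = 0.0036). They were also assigned to all 6 megakaryocyte genes with a region (2.64, adjusted permutation p = 0.0168) and 13 of 19 neutrophil maturation genes (6.84, adjusted permutation p = 0.0468). These were the 4 lists that passed. The strongest lay over S100a9 (99.97), Lyz2 (99.4), Hba-a1 (98.7) and Retnlg (98.5), next to Cacnb1 (98.5) and near Hvcn1 (95.4) and Traf1 (94.8). Dendritic cells, with 7 of 9 genes (2.92), missed the threshold (0.0504) and passed by Fisher's exact test (0.00573) and, in the permutation test, with regions within 10 kb of the gene (0.0432) or 50 kb of a gene end (0.0446). At the stricter peak significance neutrophil maturation (0.127) and megakaryocytes (0.787) did not pass. The neutrophil call was lost without Control replicate 1 (0.0792), Control replicate 3 (0.0634), MA9 replicate 2 (0.0522), MA9 replicate 3 (0.0702) or ME replicate 2 (0.0558), and dendritic cells passed without MA9 replicate 1 (0.0461). At equal list length 498 regions were lost and only neutrophil maturation passed, with 5 of 7 genes against 0.565 in random lists (adjusted permutation p = 0.0216).

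Only 14 regions were called in all 9 leukaemia libraries and in no Control library, or 352 when BN1 was left out, an alternative added after the data were seen. The count was 378 with a peak in 2 of 3 libraries, 37 with 500 bp summit windows and 191 at equal list length. The strongest lay near LOC108167320 (94.3), Ano6 (90.3), the annexin gene Anxa1 (70.7, 623 kb away), Cdh5 (69.0), Cxcl14 (57.9), the glycophorin C gene Gypc (55.6), Pigt (53.8), Bin1 (53.5), Trim2 (52.3) and Ddx10 (48.2). No list passed among these gains (0 of 18 by the adjusted permutation test, 0 unadjusted and 0 by Fisher's exact test). With a peak in 2 of 3 libraries, the Hoxa cluster and promyelocyte granules did (both adjusted permutation p = 0.0072).

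Gene-end calls of the genes named in advance are read against all protein-coding genes. Of these, 44.5% had a gene-end peak in Control, 46.8% in MA9, 28.8% in ME and 12.5% in BN1 (means of 3 libraries). A missing call in BN1 or ME is therefore not particular to a named gene. Hoxa9 had a gene-end peak in 3 MA9 and 3 ME libraries and in 0 Control and 0 BN1 libraries, and Hoxa10 in the 3 MA9 libraries alone. Meis1 was called in 3 Control and 3 MA9 libraries and in 0 others, and the Polycomb gene Bmi1 in 3 MA9 libraries and 1 Control library. Of the fusion partners, Kmt2a was called in all 12 libraries, Brd9 and Mllt1 in all but the 3 BN1 libraries, Mllt3 in 3 Control, 3 MA9 and 2 ME libraries, and Nutm1 in 0 libraries. Ptprc, which encodes the CD45 used for sorting, was called in 3 Control and 3 MA9 libraries and in 0 ME and 0 BN1 libraries, although sorted cells carry it. Among B cell genes, 15 of 20 had a gene-end peak in Control, 4 in MA9 and 0 in ME and BN1; neutrophil maturation genes numbered 16.3 ± 0.577, 8.67 ± 0.577, 3 ± 1 and 1 ± 0 of 20 in Control, MA9, ME and BN1 (SD, n = 3). Housekeeping promoters, the control for detection, were called at 15 of 18 genes in Control and MA9, 14.7 in ME and 9.33 in BN1.

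The planned log2 odds of a gene-end peak differed across groups for all 18 lists, including genes silent in blood, of which every library called 1 of 20, so this measure can differ without a difference in called list genes. As odds, 14 lists passed at equal list length, genes silent in blood again among them (adjusted exact permutation p = 0.000106). Counts of called list genes, a test added after the data were seen, passed for 16 of 18 lists as deposited and for 3 at equal list length (exact permutation test, Benjamini-Hochberg). Hox cofactors and MLL fusion targets averaged 3.67 called genes in MA9, 1 in ME and 0 in Control and BN1 (adjusted exact p = 0.00584). B cell genes averaged 2 in Control, 1 in MA9 and 0 in ME and BN1 (adjusted exact p = 0.00584), and fusion partners and complexes 4.33 in Control, 6.33 in BN1, 7.33 in MA9 and 7.67 in ME (adjusted exact p = 0.0312). The Hoxa cluster averaged 3.33 in MA9, 0.333 in ME and 0 in Control and BN1 (adjusted exact p = 0.0545), and neutrophil maturation 6 in Control and 1 in each leukaemia (adjusted exact p = 0.0545). In MA9 against Control, lost regions were assigned to 6 of 14 T cell genes (3.60 in random lists), 0 of 5 NK cell genes (1.30), 4 of 19 monocyte and macrophage genes (6.34), 2 of 6 genes of mast cells, basophils and eosinophils (1.54) and 1 of 9 interferon response genes (2.01). They were assigned to 8 of 16 Hox cofactors and MLL fusion targets (9.35), 1 of 10 genes of the list named Bmi1 neighbourhood (2.80), 4 of 17 fusion partners and complexes (6.53), 7 of 17 stem and progenitor genes (6.76), 3 of 15 housekeeping promoters (3.44) and 1 of 3 genes silent in blood (0.261), and adjusted permutation p-values of these 11 lists were 0.572 or higher.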

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

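Of the tests in this part, those of detection by strength and of lineage regions in BN1, of Meis1 regions in ME and of the Control lineage regions in MA9 were chosen after the results were seen. In several measures every MA9 library lay above and every BN1 or ME library below the 3 Control libraries. The opposite direction of these shifts was not tested as such; exact permutation tests across all 4 groups (p = 6.49e-05 for peak number and gene-end share, the smallest possible) and of BN1 against MA9 and ME (p = 0.0238 for both) tested differences in level. Between MA9 and BN1 or ME alone, the exact permutation p of 0.1 for both measures is the smallest possible.

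Peak numbers moved in opposite directions, with a difference of means of 29048 peaks between MA9 and BN1 and of 23340.0 peaks between MA9 and ME. The share of peaks at gene ends moved the other way, by 33.3 percentage points between BN1 and MA9 and 28.5 between ME and MA9. This shift did not remain at equal list length: the BN1 share was 66.2%, that of ME 75.1% and that of MA9 74.3%, so the difference between BN1 and MA9 reversed to -8.09 points. Among Hox cofactors and MLL fusion targets, the mean number of genes with a gene-end peak differed by 11 between MA9 and BN1 and by 8.33 between MA9 and ME. For the list named Bmi1 neighbourhood these differences were 6.33 and 4.33, of which 1 gene each was Spag6l, which lies on chromosome 16 and not near Bmi1 on chromosome 2. They were 9.67 and 10 for stem and progenitor genes, 11 and 5.67 for monocyte and macrophage genes, and 2 and 2 for mast cells, basophils and eosinophils. Of these 5 lists, only Hox cofactors and MLL fusion targets passed the test of counts at equal list length (3.67 genes in MA9, 1 in ME, 0 in BN1 and Control; adjusted exact permutation p = 0.00584). Outside the placed chromosomes, every MA9 library had more peaks on unplaced sequences (mean 45.7) than any Control library (mean 42.7), while ME had 5 and BN1 2.

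The BN1 lists were the shortest, and their calls followed the strength of a region in the other groups. Of the 7016 regions called in all 9 other libraries, the strongest decile was called in all 3 BN1 libraries at 99.3% and the weakest at 3.99%, which is consistent with fewer regions being detected at the same accessibility, although a loss of accessibility spread over the genome would leave the same trace. The 7016 regions are only those that the short ME lists also called. Of the strongest decile of all Control regions, 68.4% were called in all 3 BN1 libraries and 15.3% in none. For MA9 regions these values were 72.0% and 5.69%. A stricter threshold in the BN1 lists is argued against: with every list held to the highest BN1 minimum of −log10 p (5.52), ME still had 2.59 times as many peaks as BN1. A selective loss of lineage regions stays undecided, as 2 of 53 strongest Control regions of B cell, erythroid and neutrophil genes were called in BN1 and 4.40 were predicted from strength (permutation p = 0.248).

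Meis1, a Hox cofactor, had 8 regions in all 3 MA9 libraries and none of them in ME, although both leukaemias had peaks over Hoxa9. Lower detection in ME remains possible: matched on strength, 1.21 of the 8 regions were predicted in ME and 0 were called (permutation p = 0.0528), a value close to the threshold, and the regions are neighbours rather than independent. On the strongest of them, strength alone predicted a call, since 99.4% of comparable genes had theirs called. Meis1 is also called in Control, and a share of wild-type B cells and erythroid cells large enough to give peak calls in the MA9 libraries is argued against. The strongest Control regions of their genes were called in MA9 at 23.8% of the predicted number (7 of 35, 29.4 predicted). A share too small to give peak calls, and wild-type cells of other kinds, are not covered. Monocyte and macrophage genes (15 of 17 called, 13.2 predicted) and stem and progenitor genes (9 of 9, 6.98 predicted) were not short of calls in MA9. Neutrophil maturation (12 of 18, 15.7 predicted) and dendritic cells (7 of 9, 7.92 predicted) were lower and did not pass. Most of the 8 Meis1 regions had no peak in any Control library. A difference between the MLL-AF9 and MLL-ENL leukaemias at Meis1 may be biological and is a hypothesis that these lists did not settle.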

How the results depend on the processing

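Matching on strength, counts of called list genes and leaving out BN1 were chosen after seeing the data; the other alternatives were planned. List length, which no depth could be set beside, was a limit: stricter significance and equal length moved most counts because fewer peaks entered, and elsewhere the cause was not tested. Other than by leaving out a library, 158 values of the results that answer a comparison stayed on their side of the threshold or within 1.5 times, 61 moved further, 1 no longer passed and 1 reversed. Of single lists 1712 values stayed, 30 no longer passed, 15 newly passed and 5 reversed. Motif shares, with their alternatives, were not run for want of a genome sequence.

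At equal list length the gene-end share of BN1 minus Control reversed to -3.25 points (main 28.6; exact permutation p = 0.2 for this difference). Regions gained and lost became 510 and 746 for BN1 vs Control, 732 and 710 for MA9 vs Control, 779 and 809 for ME vs Control, 325 and 536 for BN1 vs MA9, 204 and 305 for BN1 vs ME, 352 and 306 for MA9 vs ME, 135 and 206 for BN1 vs MA9 and ME, and 191 and 498 for all leukaemias vs Control. Lists that passed fell to 0 gained and 0 lost in MA9 vs Control (main 3 and 5), 0 gained in ME vs Control (main 2) and 1 lost in all leukaemias (main 4). Differences of list genes from random lists reversed to 0.469 (B cells, gained, MA9), -0.137 (dendritic cells, lost, MA9), -0.409 and -0.243 (megakaryocytes, lost, MA9 and all leukaemias) and -0.186 (Hoxa cluster, gained, ME), none past the threshold. Few list genes still had a region there: 3 B cell, 1 dendritic cell and 3 megakaryocyte genes in MA9 vs Control and 1 Hoxa gene in ME vs Control. These lists could therefore hardly pass, and the reversals show little either way.

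At the stricter significance, gained and lost regions were 17 and 8876 for BN1 vs Control, 4781 and 1793 for MA9 vs Control, 198 and 6198 for ME vs Control, 2 and 12192 for BN1 vs MA9, 9 and 2149 for BN1 vs ME, 9072 and 14 for MA9 vs ME, and 0 and 2141 for BN1 vs MA9 and ME; all leukaemias lost 1790. Lists that passed were 2 lost in BN1 vs Control (main 0), 0 gained and 2 lost in MA9 vs Control, 1 lost in ME vs Control (main 0) and 2 lost in all leukaemias.

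With 500 bp summit windows, gained regions were 89 for BN1 vs Control, 60 for BN1 vs MA9, 33 for BN1 vs ME, 14 for BN1 vs MA9 and ME and 37 for all leukaemias, and 209 were lost in MA9 vs ME. With a peak in 2 of 3 libraries, they were 63 for BN1 vs Control, 43 for BN1 vs ME, 7 for BN1 vs MA9 and ME, 378 for all leukaemias and 71 lost in MA9 vs ME, and lists that passed were 1 gained in MA9 vs Control, 1 lost in ME vs Control and 2 gained in all leukaemias. In ME vs Control, 1 list passed among losses with regions within 10 kb of the gene and 2 with Fisher's exact test. Matched on strength, 1 gained and 2 lost lists passed in MA9 vs Control and 1 lost in ME vs Control. Without BN1 libraries, 352 regions were gained in the leukaemias. Concordance as a share of overlapping peaks was 0.0192 (exact permutation p = 0.235, no longer past the threshold). Gene-end calls passed for 18 lists as odds (14 at equal length) and for 16 as counts (3 at equal length).

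Leaving out 1 library gave these ranges: variance between groups in peak number 0.996 to 0.998, concordance 0.518 to 0.549, gene-end share difference 28.1 to 29.1. Gained regions ranged from 36 to 50 (BN1 vs Control), 9252 to 10431 (MA9 vs Control), 400 to 501 (ME vs Control), 14 to 17 (BN1 vs MA9), 20 to 31 (BN1 vs ME; 31 without BN1 replicate 1), 18162 to 19809 (MA9 vs ME), 4 to 6 (BN1 vs MA9 and ME) and 14 to 21 (all leukaemias). Lost regions, in the same order, ranged from 19033 to 20748, 5317 to 6241, 14648 to 16298, 23275 to 24930, 3553 to 4326, 47 to 61, 3537 to 4289 and 5313 to 6236. Lists that passed ranged from 1 (without MA9 replicate 3) to 4 gained and 4 to 5 lost in MA9 vs Control, 0 to 1 lost in ME vs Control (1 without Control replicate 2, MA9 replicate 2 or ME replicate 1), 0 to 1 lost in BN1 vs MA9 (1 without MA9 replicate 1 or 3), 3 to 5 lost in all leukaemias, and 17 to 18 as odds.

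With a replicate block, exact permutation p-values for variance between groups in peak number (0.996), concordance (0.523) and gene-end share (28.6 points) were 0.00174, the smallest that 576 blocked splits can give, and region counts were identical by construction (highest of the other blocked splits 37, MA9 vs Control). Replicate numbers did not pair the libraries: correlations between same-numbered libraries of different groups ran from -0.0256 to 0.014, and 2 of 12 libraries correlated best with their own number.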

Other observations

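The gene families, the heat-shock and histone groups, the counts per chromosome and all tests on them were chosen after the data were seen. The family stems were refined after an initial scan, and histone genes were grouped after several had appeared among the strongest BN1 losses. The S100a genes were grouped by a rule of their own, as the general stem rule does not form that family.

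Gene families named by symbol stem were compared at equal strength. The S100a family of calcium-binding proteins had its strongest Control region called in MA9 at 5 of 10 genes where 9.17 were predicted (adjusted permutation p = 0.012) and in ME at 1 of 10 where 5.77 were (adjusted permutation p = 0.024). S100a9 was among the strongest losses in both and the family had its own rule, so the S100a p-values do not come from a blind scan. The C-type lectin genes (Clec), many of which encode receptors of myeloid cells, were called in ME at 1 of 20 genes where 6.13 were predicted (adjusted permutation p = 0.024). Interferon-inducible genes (Ifi) were called in MA9 at 3 of 10 where 8.05 were predicted (adjusted permutation p = 0.012), whereas the interferon response list did not differ there (8 of 9 called, 8.22 predicted). These were 2 of 120 families in each comparison; neighbouring members of a family share regions of the genome and are not independent.

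In BN1, 0 of 120 families passed against Control by the adjusted permutation test and 4 had an unadjusted p under 0.05. Heat-shock protein genes (Hspa) were called in all 3 BN1 libraries at 9 of 12 genes where 5.43 were predicted, and histone genes at 7 of 32 where 14.6 were (both adjusted permutation p = 0.132). Against MA9, Hspa genes were called at 9 of 10 where 6.04 were predicted (adjusted permutation p = 0.16) and histone genes at 7 of 33 where 10.3 were (unadjusted permutation p = 0.115, adjusted 1). Against ME, Hspa genes were called at 9 of 10 where 5.94 were predicted (unadjusted permutation p = 0.003) and histone genes at 7 of 30 where 11.6 were (adjusted permutation p = 0.21); none passed.

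Called regions were not spread evenly over the chromosomes in ME. Against the number predicted from the strength of Control regions, ME calls stood at 1.19 ± 0.0464 on chromosome 15, 1.23 ± 0.0474 on chromosome 18 and 1.15 ± 0.0366 on chromosome 19 (SD, n = 3), and between 0.92 and 1.06 on the other 16 chromosomes (adjusted exact permutation p across BN1, MA9 and ME = 0.0475, 0.017 and 0.0452). The test alone does not single out these chromosomes, which were picked after a first look: 10 of 19 passed with Control regions and 2 of 19 with MA9 regions. Extra copies of these chromosomes in ME stay undecided: calls exceeded the prediction in 9 of 9 segments (3 of equal region number per chromosome), against Control and against MA9 regions alike, but the chromosomes were picked for their excess, and picking 3 in the same way for BN1 gave 6 of 9. Of the 3, only chromosome 18 passed with MA9 regions (adjusted exact permutation p across Control, BN1 and ME = 0.0848, 0.0339 and 0.0776), where Control itself stood at 0.903 ± 0.0116, under its lowest mean of 0.966 on the other 16 chromosomes. A few dense loci are argued against, since the ratio was 1.13 or higher without the 10 Mb window of most excess calls on each chromosome, and so is better detection of gene-rich chromosomes, since chromosome 7, the most gene-dense, stood at 0.945 on average over both references. BN1 shared part of the excess: with Control regions it stood at 1.07 ± 0.0739 on chromosome 15 (1.5 in the first segment), 1.09 ± 0.0429 on chromosome 18 (1.25 in the first segment) and 1.19 ± 0.0823 on chromosome 19, and with MA9 regions at 0.953, 0.977 and 1.17. MA9 stood at 1.004 on chromosome 19, and an excess common to ME and BN1 would not call for extra copies in ME. Read depth per chromosome, which would decide it, was not used here.

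Other splits of the same libraries showed what regrouping gives; all were planned. With 10 splits of 3 libraries against 3, the real one included, the splits are too few for a share under 0.05, and in each comparison 1 split, the real one, reached its own value. The real totals of gained and lost regions, with the highest of the other splits, were 19069 and 7 for BN1 against Control, 14569 and 55 for MA9 against Control, 15048 and 10 for ME against Control, 23289 and 1 for BN1 against MA9, 3572 and 19 for BN1 against ME, and 18209 and 2 for MA9 against ME. The lists that passed numbered 8 against 0 for MA9 and 2 against 0 for ME, each compared with Control. For BN1 against MA9 and ME, 2 of 84 splits gave as many regions as the real 3540. The other was MA9 against BN1 and ME, with 18065, which follows the long MA9 lists. For all leukaemias against Control, 1 of 100 drawn splits reached the real 5327 regions (highest other 3157, BN1 against the rest) and 1 of 100 the 4 lists (highest other 0). MA9 against the other 9 libraries, which was not drawn, gives 8577 regions. In both comparisons only a random mix of libraries is argued against, as such splits rarely give regions under the rule (median of the other splits 0). The splits cannot tell whether list length or the fusion set the groups apart.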
